A study of Mus musculus with 8 samples.

How the data were processed

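RNA-seq counts were analysed for choroid plexus, the secretory epithelium and underlying stroma that makes cerebrospinal fluid, from mouse embryos of the outbred CD1 strain at embryonic day E18.5. Per the labels, 2 factors were crossed: region (telencephalic, from the lateral ventricles, or hindbrain, from the fourth ventricle) and preparation (whole choroid plexus, or epithelial cells purified by fluorescence-activated sorting). The sorted cells carried a red fluorescent reporter driven by the promoter of Ttr, the transthyretin gene. Each of the 4 groups held 2 libraries, described as biological replicates in the series' design text. The same text states that the 2 regions were taken from the same brains. The libraries were taken to come from 4 brains, or pools of brains, 2 per preparation: the text does not say whether embryos were pooled, and Xist and Y-linked genes had counts in every library. Preparation was therefore not compared within a brain.

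Per the labels' protocols, total RNA was isolated with a silica-column kit for small samples. It was converted to cDNA and pre-amplified with the NuGEN Ovation RNA-seq System V2 and made into paired-end libraries with the Illumina TruSeq v2 chemistry. These protocols mark no strand, so reads from overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Bowtie2 2.0.5, HTSeq, DESeq 1 and the mouse build mm9. The gene annotation, the strand setting and the HTSeq version are not given in the sources used here. The deposited values are whole-number read counts per gene symbol, not normalized. The table held 23284 genes and 8 columns, and each column name matched 1 sample. Genes are named by symbol and no coordinates are given, because a genome of the build mm9 was not used here. Genes with near-identical copies, such as the globins, and overlapping pairs such as Six3 and Six3os1 are uncertain at the level of the single gene.

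Total counts ranged from 8849053 to 31613434 per library. The reads were pre-amplified and carried no molecular identifiers, so every counting interval or floor given covers counting error only. Replicates of a group differed by more than sampling noise: the chi-square per degree of freedom between replicates was 5.42 for telencephalic whole tissue, 13.03 for hindbrain whole tissue, 16.7 for telencephalic sorted cells and 64.49 for hindbrain sorted cells. None of the libraries was a copy of another. Spearman correlations across genes between replicates lay between 0.98 and 0.989.

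The counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 15698. Libraries were scaled by TMM factors. A quasi-likelihood model with 4 group means was fitted to all 8 libraries, so that the groups shared 1 estimate of the spread. Quasi-likelihood F tests gave 6 contrasts: hindbrain minus telencephalic in whole tissue, the same in sorted cells, the difference between those effects (the interaction), sorted minus whole in each region, and the region effect averaged over both preparations. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to be called. Expression is given as CPM, edgeR's counts relative to the TMM-scaled library size, as mean ± SD over the 2 libraries of a group, and fold changes as log2 values ± SE of the fit.

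Gene lists were fixed before the data were examined, as were the tests, the main alternatives and the rule for naming genes. Of 24 lists 23 were tested, and the remaining list, of sex-linked genes, was kept as a check. Symbols of 376 of the 377 distinct list genes were found in the table, 8 of them under an older name. The tested lists covered Hox genes, hindbrain and midbrain-hindbrain boundary regulators, forebrain regulators, Hedgehog, Wnt and BMP signalling, the retinoic acid pathway, choroid epithelial identity, ion and water transport, secreted factors, tight junctions, motile cilia, cell cycle, interferon response, immediate early and heat shock genes, and nuclear-encoded oxidative phosphorylation. Markers of other cell types covered mesenchymal, endothelial, mural, macrophage, erythroid, neuronal and neural progenitor or glial cells. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 23 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of called members are also given when adjusted over the list alone.

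The text names genes from 5 rules: the 6 called genes per direction with the largest fold change in each region and preparation comparison (mean of at least 10 CPM in the higher group, groups not overlapping, unnamed and predicted genes left out); up to 4 called members per list by adjusted p, or the 2 most abundant where fewer than 2 were called; 8 genes per direction shared by both region comparisons, by the smaller of the 2 fold changes; 6 per direction for the interaction by adjusted p; and Ttr. Some genes that these rules pick are not reported here. Where a list offered several, those called in every alternative were preferred, a choice made after the values were seen. A fold against a group with 0 counts is given as a lower bound, computed against 3 counts over the group. Against a group with 1 to 3 counts the ratio is given with its 95% counting interval.

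Deviations of same-brain libraries from their group means correlated across genes at 0.19 in whole tissue and 0.14 in sorted cells. The pairing was taken from the design text, by replicate number, which the text does not spell out. The fit with brain as a block was an alternative, and its value stands beside a result where it changed the call or moved a count by over 1.5 times. For the preparation comparisons, where brain and preparation are confounded, the block was a correlation estimated by limma-voom. Other alternatives were median-of-ratios (RLE) scaling, DESeq2 1.42.0, no low-count filter, a filter of 1 CPM in 2 libraries, a fit to the 4 libraries of a comparison, a test against a fold change of 1.5, and leaving out each library in turn. With 1 library left out, the remaining library of that group was assumed to vary like those of the other groups. Scaling by library totals, leaving out Ttr and Rn45s, leaving out genes depleted by the sort, limma-voom without a block for the preparation comparisons and camera on the interaction were chosen after the data were examined.

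The tests were checked on simulated counts drawn from the genes' means and the library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Each gene had the same spread in all simulated groups. The real groups differed in replicate noise, with a chi-square per degree of freedom from 5.42 to 64.49. Error rates under such uneven spread were therefore not checked. For the region comparison in whole tissue 66% of the 2-fold and 89% of the 4-fold changes were called, and in sorted cells 65% and 88%. For the interaction the shares were 50% and 79%, for preparation in telencephalic tissue 59% and 91%, and for preparation in hindbrain tissue 65% and 96%. For the averaged region effect, where the change was put into 1 preparation and so appeared at a lower size, they were 35% and 84%. False calls made up 4.9%, 5%, 8.5%, 11.2%, 6.9% and 6.3% of the calls in the same order. Camera called 2 of 2 changed lists and 0 of 18 unchanged lists. The simulated genes varied independently of one another, and the raised values of the changed lists were drawn with a small fixed spread. This check therefore cannot show how often camera errs at its preset correlation where the genes of a list vary together.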

Results

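Expression was measured by RNA sequencing in choroid plexus of mouse embryos at stage E18.5. The tissue came from the lateral ventricles (telencephalic) or the fourth ventricle (hindbrain), either whole or as sorted epithelial cells that carried a red fluorescent reporter of Ttr. Each of the 4 groups held 2 biological replicates, so n = 2 for every group value below. Total counts were 15583831 and 8849053 for telencephalic whole tissue and 21932900 and 18947870 for hindbrain whole tissue. They were 31613434 and 18562464 for telencephalic sorted cells and 26710018 and 29231556 for hindbrain sorted cells. The first principal component, with 50.1% of the variance, parted the preparations, and the second, with 24.7%, parted the regions. Transthyretin (Ttr), the main secreted protein of the choroid epithelium, reached 179600 ± 10570 CPM (SD) in telencephalic whole tissue, 140100 ± 1064 in hindbrain whole tissue, 269400 ± 17520 in telencephalic sorted cells and 184800 ± 36550 in hindbrain sorted cells. The ribosomal precursor Rn45s stood at 41010 ± 341 and 36570 ± 785 CPM in telencephalic and hindbrain whole tissue, against 150400 ± 23120 and 92200 ± 41240 in the sorted cells of the same regions. Fold changes are log2 values ± SE of the fit, and each adjusted p for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

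The first comparison asked how the whole choroid plexus of the hindbrain differs from that of the telencephalon, as the series concerns positional identity and regional production of cerebrospinal fluid. Hindbrain whole tissue carried Hox transcripts that telencephalic tissue lacked or nearly lacked. Hoxa3 and Hoxb3, which pattern the hindbrain, had 0 counts in both telencephalic libraries and were at least 39.2-fold and 34-fold higher in hindbrain tissue, at 4.51 ± 0.64 and 3.97 ± 0.60 CPM. Hoxa2 was 187-fold higher (95% counting interval 33.3 to 7410). Of 7 tested Hox genes 6 were higher, 0 lower and 1 not called (6 when adjusted over the list alone; camera adjusted p = 5.66e-13). Among hindbrain and midbrain-hindbrain boundary regulators 4 of 10 were higher and 6 not called (9 called when adjusted over the list alone; camera adjusted p = 3.89e-14). They included Meis1, a Hox cofactor, at 5.96 ± 0.42 (adjusted p = 5.19e-06), and En2, a boundary transcription factor, at 3.76 ± 0.45 (adjusted p = 0.000252). The Iroquois gene Irx2 was at least 27.6-fold higher. Forebrain regulators went the other way, with 8 of 13 lower in hindbrain tissue, 0 higher and 5 not called (10 called when adjusted over the list alone; camera adjusted p = 1.5e-48). Dmrt3, a doublesex-related factor of the dorsal telencephalon, fell from 37.6 ± 1.4 to 0.108 ± 0.019 CPM, a log2 change of -8.36 ± 0.46 (adjusted p = 7.44e-07). Six3, which specifies anterior forebrain, changed by -6.10 ± 0.26 (adjusted p = 1.58e-07), and Otx1 by -3.28 ± 0.26. Dmrta2 and Emx2 were 201-fold (68.1 to 978) and 133-fold (45 to 651) lower. These 3 lists kept their calls when camera used an estimated correlation (adjusted p = 0.0419, 0.0137 and 0.00217), and no other list of this comparison did.

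**Figure D1:**
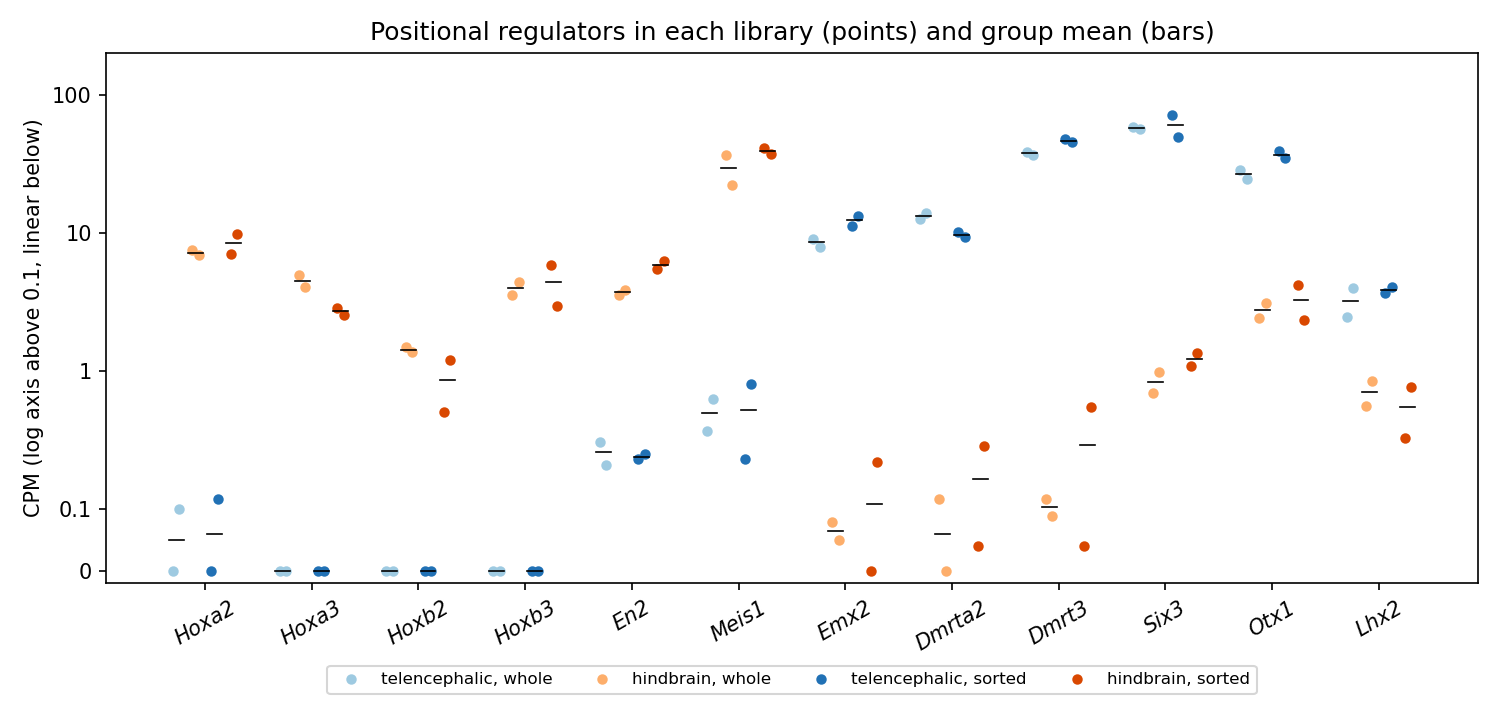
Expression in CPM (log axis above 0.1, linear below) of 12 positional regulators in each of the 8 libraries (points), with the mean of each group as a bar. Hoxa3 and Hoxb3 lie at 0 in all 4 telencephalic libraries and Dmrt3 stands at 37.6 in telencephalic against 0.108 in hindbrain whole tissue.

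Signalling ligands of the patterning pathways also differed in whole tissue. The BMP-family ligand Gdf7, a roof plate signal, rose from 0.175 ± 0.099 to 82.1 ± 29 CPM in hindbrain tissue (8.69 ± 0.57, adjusted p = 2.29e-06), and Shh, the Hedgehog ligand, from 0.245 ± 0.35 to 14.5 ± 3.4 CPM (5.56 ± 0.50, adjusted p = 3.7e-05). In the Hedgehog list 5 of 13 genes were higher, 1 lower and 7 not called (8 called when adjusted over the list alone), with Hhip, a Hedgehog target and antagonist, at 1.53 ± 0.22. Its camera adjusted p of 0.000116 became an adjusted p = 0.0907 with an estimated correlation. Wnt signalling was split: 5 of 16 genes were higher, among them Wnt5a at 1.56 ± 0.11 (adjusted p = 7.11e-06) and Wnt4 at 2.18 ± 0.32, and 3 were lower, among them the R-spondins Rspo2 at -3.71 ± 0.20 and Rspo3 at -2.10 ± 0.27, which enhance Wnt signals. For this list 8 were not called, 8 were called when adjusted over the list alone, and camera gave an adjusted p of 0.228. Of 16 BMP genes 2 were higher, 1 was lower and 13 were not called (5 called when adjusted over the list alone; camera adjusted p = 0.0271, or adjusted p = 0.182 with an estimated correlation). Id4, a BMP target, changed by 1.44 ± 0.16. Of 12 retinoic acid genes 3 were higher, 1 lower and 8 not called (5 called when adjusted over the list alone; camera adjusted p = 0.0271, or adjusted p = 0.182 with an estimated correlation). Aldh1a2, which makes retinoic acid, changed by 4.27 ± 0.38, while the retinol dehydrogenase Rdh10 changed by -0.82 ± 0.11. The BMP and retinoic acid list calls were lost without telencephalic whole replicate 2 (adjusted p = 0.123 and 0.179) and without hindbrain whole replicate 1 (0.0697 and 0.11).

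The secreted factor, transport and epithelial lists differed gene by gene. Penk, the enkephalin precursor, rose from 6.88 ± 2.0 CPM in telencephalic to 682 ± 46 CPM in hindbrain tissue (6.59 ± 0.33, adjusted p = 3.68e-07). Sod3, an extracellular superoxide dismutase, and Igf1 were also higher, at 1.59 ± 0.14 and 1.00 ± 0.11, and the extracellular chaperone Clu was lower, at -0.71 ± 0.11. Of 22 secreted factors 7 were higher, 4 lower and 11 not called (14 called when adjusted over the list alone). Camera gave an adjusted p of 0.0334, upward, with a list mean of 0.37 and a median of -0.11, and an adjusted p = 0.182 with an estimated correlation. The sodium-driven bicarbonate transporter Slc4a10 rose from 351 ± 3.7 to 1200 ± 47 CPM (1.77 ± 0.11, adjusted p = 1.42e-06). In the ion and water transport list 2 of 19 genes were higher, 1 lower and 16 not called (3 called when adjusted over the list alone; camera adjusted p = 0.271). The lysophospholipase Enpp2 rose from 1680 ± 28 to 3730 ± 340 CPM (1.15 ± 0.12, adjusted p = 0.000141). The choroid epithelial identity list held 2 higher, 3 lower and 11 uncalled genes of 16 (9 called when adjusted over the list alone; camera adjusted p = 0.409). Ttr itself was not called, at -0.36 ± 0.13 (adjusted p = 0.144), though it was called without the low-count filter (0.0377), with the 4 libraries of the comparison alone (0.0292) and without hindbrain sorted replicate 2 (0.0373). Of 12 tight junction genes 3 were higher, 0 lower and 9 not called (8 called when adjusted over the list alone; camera adjusted p = 0.596 with a mean of 0.14 and a median of -0.06). Of 22 motile cilia genes 3 were lower, including the axonemal dynein Dnahc11 at -0.69 ± 0.11, 0 were higher and 19 were not called (5 called when adjusted over the list alone; camera adjusted p = 0.014, or adjusted p = 0.419 with an estimated correlation). The secreted factor call was lost without telencephalic whole replicate 2 (0.108) and hindbrain whole replicate 1 (0.0515), and the cilia call without telencephalic whole replicate 1 (0.126).

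Markers of other cell types were present in whole tissue, and some of them differed by region. Of 15 mesenchymal markers 6 were higher in hindbrain tissue, 1 lower and 8 not called (12 called when adjusted over the list alone; camera adjusted p = 4.67e-05, or adjusted p = 0.19 with an estimated correlation). The fibrillar collagen gene Col1a1 changed by 1.68 ± 0.23. Macrophage markers had 1 of 15 higher and 14 not called (3 called when adjusted over the list alone; camera adjusted p = 0.0259, or adjusted p = 0.216 with an estimated correlation). Erythroid markers had 2 of 7 higher and 5 not called (4 when adjusted over the list alone; camera adjusted p = 0.00256, or adjusted p = 0.119 with an estimated correlation). Neuronal markers had 2 of 14 higher, 2 lower and 10 not called (9 when adjusted over the list alone; camera adjusted p = 0.00395, or adjusted p = 0.147 with an estimated correlation). The synaptic vesicle gene Syt1 changed by 1.59 ± 0.17. Neural progenitor and glial markers had 2 of 12 higher and 10 not called (3 when adjusted over the list alone; camera adjusted p = 0.00645, or adjusted p = 0.182 with an estimated correlation). The glutamate transporter Slc1a3 changed by 1.41 ± 0.15. Endothelial markers had 1 of 14 higher and 13 not called (camera adjusted p = 0.596; 1 when adjusted over the list alone). Mural cell markers had 0 of 12 called (camera adjusted p = 0.808, downward, with a mean of 0.02 and a median of -0.06; 0 when adjusted over the list alone). Cell cycle genes had 0 of 20 called but a camera adjusted p of 0.000306, upward (4 when adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). Interferon response had 1 of 15 higher (camera adjusted p = 0.43; 2 when adjusted over the list alone), immediate early and heat shock genes 1 of 20 (0.0969; 1 when adjusted over the list alone) and nuclear-encoded oxidative phosphorylation 0 of 18 (0.0447; 2 when adjusted over the list alone; adjusted p = 0.522 with an estimated correlation). The macrophage call was lost without telencephalic whole replicate 1 (0.0756) and hindbrain whole replicate 1 (0.0791), the progenitor call without telencephalic whole replicate 2 (0.108) and hindbrain whole replicate 1 (0.0697), and the oxidative phosphorylation call without any library but telencephalic whole replicate 1 or hindbrain whole replicate 2 (0.0575 to 0.389). The immediate early list passed without telencephalic whole replicate 1 (0.0116) and hindbrain whole replicate 2 (0.0327).

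In whole tissue 909 of 15698 tested genes were called, 524 higher and 385 lower in the hindbrain, and 473 of them differed more than 2-fold. Beyond the lists, the largest changes included the GDNF receptor Gfra1 at 4.84 ± 0.58 and the neutrophil granule gene Ngp at 4.83 ± 0.59, both higher in hindbrain tissue. The membrane lectin gene Chodl and the matrix gene Vit were lower, at -4.65 ± 0.27 and -4.01 ± 0.31. The count was 316 without telencephalic whole replicate 1, 380 without telencephalic whole replicate 2, 561 without hindbrain whole replicate 1 and 476 without hindbrain whole replicate 2. It was 1587 with the 4 libraries of the comparison alone and 280, 71.1% of them higher, against a fold change of 1.5; with library totals as the scale 70.7% of the called genes were higher instead of 57.6%.

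The same regional contrast in sorted epithelial cells asked which differences belong to the reporter-positive cells. The positional regulators differed in the sorted cells too. Hoxa3 and Hoxb3 had 0 counts in both telencephalic libraries and were at least 38.6-fold and 63-fold higher in hindbrain cells, and Hoxa2 was 178-fold higher (95% counting interval 49.1 to 1480). Of 7 tested Hox genes 6 were higher and 1 not called (6 when adjusted over the list alone; camera adjusted p = 1.85e-09). Hoxb4 changed by 3.05 ± 0.56. Hindbrain and boundary regulators had 8 of 10 higher and 2 not called (9 when adjusted over the list alone; camera adjusted p = 2.35e-15), with Meis1 at 6.40 ± 0.39, En2 at 4.61 ± 0.41 and Irx2 146-fold higher (25.9 to 5800). Forebrain regulators had 10 of 13 lower, 0 higher and 3 not called (11 called when adjusted over the list alone; camera adjusted p = 1.11e-33). Dmrt3 changed by -7.28 ± 0.39, Emx2 by -6.73 ± 0.54, Six3 by -5.63 ± 0.24 and Otx1 by -3.49 ± 0.25. With an estimated correlation these 3 lists kept their calls (adjusted p = 0.0405, 0.0121 and 0.00451), as did the endothelial, mural and macrophage lists below, and no other list of this comparison did.

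Signalling genes of the same pathways differed in sorted cells. Gdf7 rose from 0.565 ± 0.69 to 75.0 ± 0.85 CPM (7.34 ± 0.47, adjusted p = 1.57e-06) and Shh from 0.15 ± 0.051 to 8.46 ± 0.34 CPM (5.84 ± 0.53, adjusted p = 1.48e-05). The Hedgehog effector Gli1 changed by 4.96 ± 0.60 and Hhip by 3.47 ± 0.24. In the Hedgehog list 5 of 13 genes were higher, 2 lower and 6 not called (8 called when adjusted over the list alone; camera adjusted p = 0.00185, or adjusted p = 0.0624 with an estimated correlation). Wnt5a rose from 46.3 ± 3.0 to 244 ± 8.8 CPM (2.40 ± 0.12, adjusted p = 1.53e-07) and Rspo2 fell from 41.8 ± 4.6 to 1.11 ± 0.084 CPM (-5.22 ± 0.21, adjusted p = 3.1e-08). The Wnt list held 6 higher, 3 lower and 7 uncalled genes of 16 (9 called when adjusted over the list alone; camera adjusted p = 0.688, upward, with a mean of 0.18 and a median of -0.15). Of 16 BMP genes 6 were higher, 2 lower and 8 not called (10 called when adjusted over the list alone; camera adjusted p = 0.0404, or adjusted p = 0.212 with an estimated correlation), with Bmp2 at 4.55 ± 0.66 and Bmp5 at -0.78 ± 0.16. The BMP call was lost without telencephalic sorted replicate 1 (adjusted p = 0.115) and hindbrain sorted replicate 2 (0.0571). Of 12 retinoic acid genes 5 were higher, 2 lower and 5 not called (7 called when adjusted over the list alone; camera adjusted p = 0.208). Aldh1a2 changed by 3.22 ± 0.52, the receptor gene Rarb by 1.40 ± 0.18 and Rdh10 by -1.19 ± 0.11. Most Aldh1a2 transcripts were lost with the sort. The gene had 1068 counts in hindbrain whole tissue and 98 in hindbrain sorted cells, and 31 and 8 in the telencephalic groups. Its difference therefore cannot be assigned to the epithelial cells.

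Secreted, transport and epithelial list genes differed in sorted cells as well. A difference there does not by itself place a gene in the epithelial cells. Macrophage and mesenchymal markers had sorted-to-whole medians of only -0.11 and -0.28 in hindbrain tissue (members with at least 10 counts in every group). Penk had 31248 counts in hindbrain whole tissue and 23680 in the more deeply sequenced hindbrain sorted cells, so its cell of origin stays open. Penk rose from 10.3 ± 3.4 to 432 ± 180 CPM (5.42 ± 0.31, adjusted p = 5.28e-07), Slc4a10 from 444 ± 19 to 1390 ± 91 CPM (1.65 ± 0.11, adjusted p = 1.82e-06) and Slc4a5, a second bicarbonate transporter, from 689 ± 97 to 1230 ± 110 CPM (0.84 ± 0.14, adjusted p = 0.00158). The folate receptor Folr1 fell from 1120 ± 27 to 682 ± 47 CPM (-0.72 ± 0.10, adjusted p = 0.000539). Ttr was lower in hindbrain cells, at -0.54 ± 0.13 (adjusted p = 0.0118), a call lost without telencephalic sorted replicate 1 (-0.48, adjusted p = 0.0762), without hindbrain sorted replicate 1 (-0.36, 0.0938) and with library totals as the scale (-0.35, 0.0621). The choroid epithelial identity list had 2 of 16 higher, 6 lower and 8 not called (8 when adjusted over the list alone; camera adjusted p = 0.0475). That list passed neither with an estimated correlation (adjusted p = 0.179), nor with brain as a block (0.0509), nor without any 1 of the 4 sorted libraries (0.0586 and 0.0963 without telencephalic replicates 1 and 2, 0.0861 and 0.0557 without hindbrain replicates 1 and 2). Ion and water transport had 2 of 19 higher, 2 lower and 15 not called (4 when adjusted over the list alone; camera adjusted p = 0.672 with a mean of 0.10 and a median of -0.08). Secreted factors had 7 of 22 higher, 5 lower and 10 not called (12 when adjusted over the list alone; camera adjusted p = 0.0539). The list passed with brain as a block (0.0331) and when any library except a telencephalic sorted one was left out (0.0124 to 0.0467). Tight junction genes had 4 of 12 higher, 4 lower and 4 not called (8 when adjusted over the list alone; camera adjusted p = 0.98 with a mean of 0.09 and a median of -0.02), with Marveld2 at 0.96 ± 0.13 and the claudin Cldn3 at -0.97 ± 0.17. Motile cilia genes had 2 of 22 higher, 1 lower and 19 not called (2 when adjusted over the list alone; camera adjusted p = 0.98), and oxidative phosphorylation 0 of 18 called (camera adjusted p = 0.716; 0 when adjusted over the list alone).

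Macrophage, mural, endothelial and mesenchymal markers and stress-response genes were higher in hindbrain than in telencephalic sorted cells, whereas neuronal markers were lower (camera adjusted p = 0.0221, or adjusted p = 0.179 with an estimated correlation). All 15 macrophage markers were higher, with a list median of 2.12 (15 when adjusted over the list alone; camera adjusted p = 6.22e-20, or adjusted p = 0.0178 with an estimated correlation). The complement gene C1qb rose from 2.98 ± 0.18 to 15.5 ± 0.74 CPM (2.38 ± 0.18, adjusted p = 4.71e-06), and the protease gene Ctss changed by 2.81 ± 0.28. Mural cell markers had 8 of 12 higher and 4 not called (8 when adjusted over the list alone; camera adjusted p = 1.04e-12, or adjusted p = 0.015 with an estimated correlation). The pericyte gene Rgs5 changed by 3.28 ± 0.27. Endothelial markers had 6 of 14 higher, 1 lower and 7 not called (10 when adjusted over the list alone; camera adjusted p = 1.82e-06, or adjusted p = 0.0281 with an estimated correlation). The cadherin Cdh5 changed by 2.09 ± 0.14. Mesenchymal markers had 12 of 15 higher, 1 lower and 2 not called (14 when adjusted over the list alone; camera adjusted p = 1.07e-15, or adjusted p = 0.0527 with an estimated correlation). Col1a1 changed by 2.72 ± 0.25. Immediate early and heat shock genes had 15 of 20 higher and 5 not called (18 when adjusted over the list alone; camera adjusted p = 9.04e-15, or adjusted p = 0.0624 with an estimated correlation), with Fosb at 1.82 ± 0.18 and Klf6 at 2.11 ± 0.16. Cell cycle genes had 8 of 20 higher and 12 not called (11 when adjusted over the list alone; camera adjusted p = 9.6e-05, or adjusted p = 0.179 with an estimated correlation). The proliferation marker Mki67 changed by 1.35 ± 0.20.

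Among the remaining lists in sorted cells, erythroid markers had 2 of 7 higher and 5 not called (2 when adjusted over the list alone; camera adjusted p = 0.00708, or adjusted p = 0.0903 with an estimated correlation). The embryonic globin gene Hba-x changed by 4.17 ± 0.35. Neuronal markers had 1 of 14 higher, 5 lower and 8 not called (7 when adjusted over the list alone). The neurofilament gene Nefm changed by -1.74 ± 0.30. Progenitor and glial markers had 6 of 12 higher and 6 not called (6 when adjusted over the list alone; camera adjusted p = 0.0475, or adjusted p = 0.22 with an estimated correlation). Interferon response genes had 2 of 15 higher, 1 lower and 12 not called (7 when adjusted over the list alone; camera adjusted p = 0.0353, or adjusted p = 0.381 with an estimated correlation). The oligoadenylate synthetase-like gene Oasl2 changed by 2.82 ± 0.30. The interferon call was lost without telencephalic sorted replicate 1 (0.217) and hindbrain sorted replicate 2 (0.264), and the neuronal call without telencephalic sorted replicate 2 (0.108) and hindbrain sorted replicate 2 (0.0772). The progenitor and glial call was lost without telencephalic whole replicate 2 (0.0637), hindbrain whole replicate 2 (0.0737), telencephalic sorted replicate 2 (0.101), hindbrain sorted replicate 1 (0.112) and hindbrain sorted replicate 2 (0.0538).

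In sorted cells 2383 genes were called, 1422 higher and 961 lower in the hindbrain, and 1217 of them differed more than 2-fold. The Notch-related ligand gene Dlk1 was among the largest, at 4.90 ± 0.20, and the neuritin gene Nrn1 fell by 5.04 ± 0.46 on the log2 scale. Without genes that the sort had depleted at least 2-fold in either region, among them 70 of 89 tested markers of other cell types, 1435 were called. That filter uses the sorted libraries of the comparison itself, so it also takes out genes for being low in 1 of the regions, and the direction of the remaining calls is not compared. The count was 1051 without telencephalic sorted replicate 1 and 1545 without telencephalic sorted replicate 2, 1460 with the 4 libraries of the comparison alone, and 788, 75.5% of them higher, against a fold change of 1.5. With library totals as the scale all genes shifted by a median of 0.20 and 83.5% of the called genes were higher instead of 59.7%. The larger count here, 2383, than in whole tissue, 909, depended on the shared estimate of the spread. Fits to the 4 libraries of each comparison gave 1460 here and 1587 in whole tissue.

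**Figure D2:**
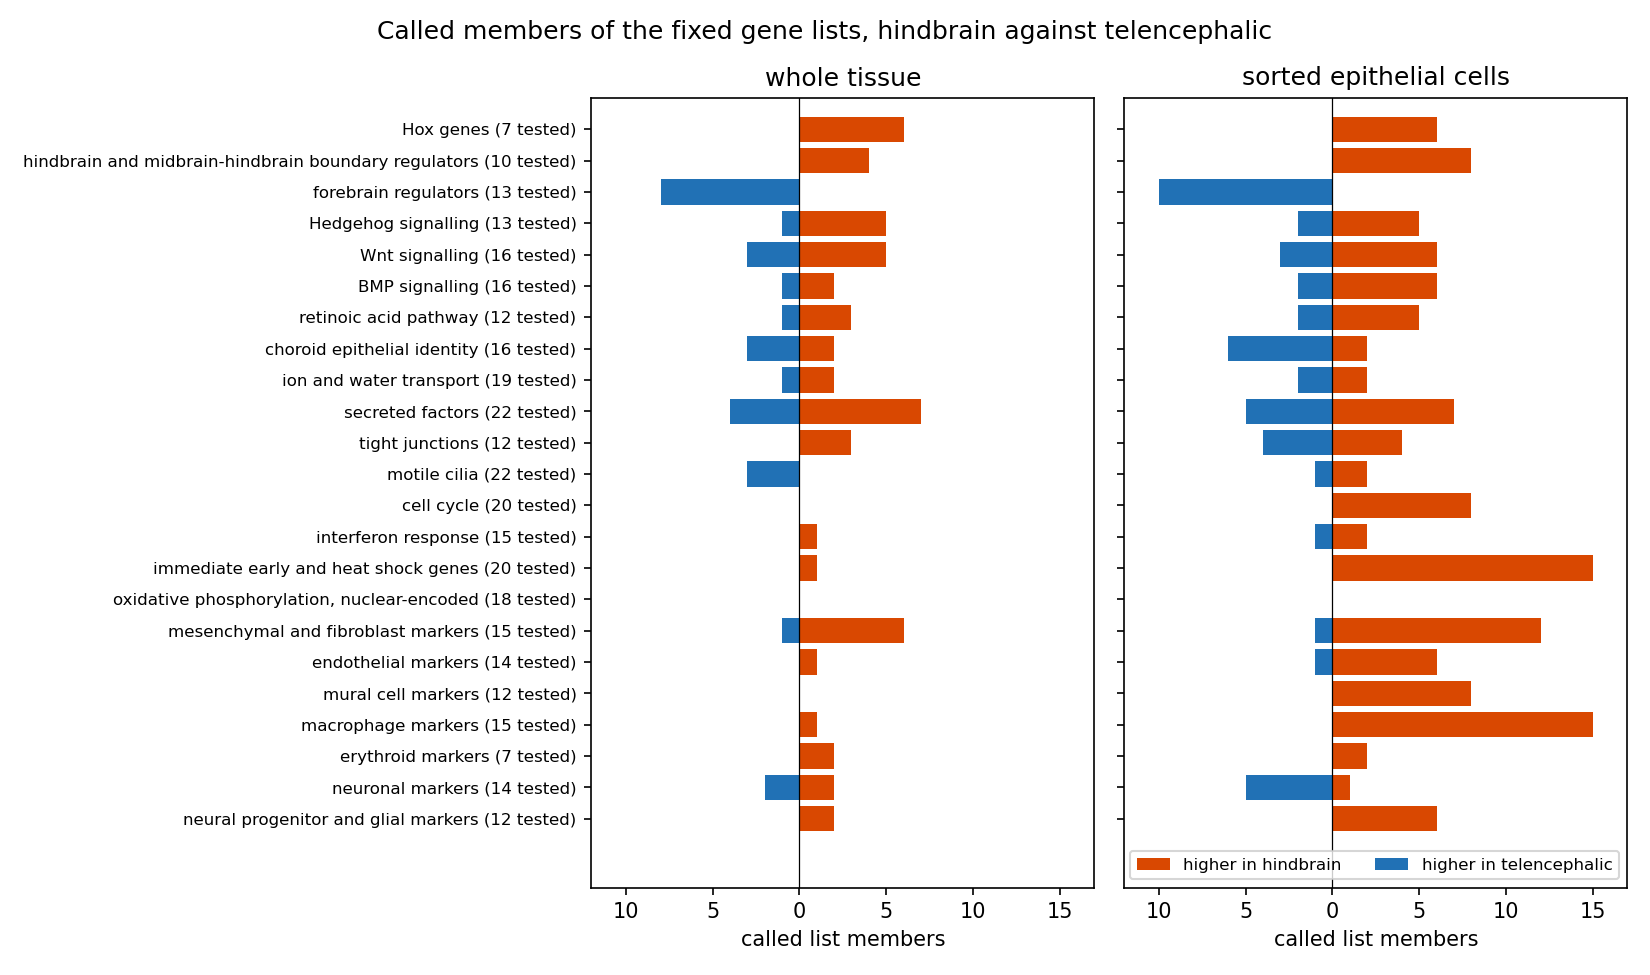
Number of called members of each of the 23 tested lists (horizontal axis) that were higher in hindbrain (right of 0) or in telencephalic choroid plexus (left of 0), in whole tissue and in sorted cells. Forebrain regulators lie to the left in both panels, with 8 and 10 called members, and macrophage markers go from 1 called member in whole tissue to 15 in sorted cells.

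Genes called in both preparations differed by region in whole tissue and in the sorted cells. They were led by Gdf7, Meis1, Shh, Penk, Gfra1, Aldh1a2, the neurotrophin receptor Ngfr (3.86 ± 0.25 in whole tissue and 3.96 ± 0.25 in sorted cells) and the microfibril-associated Thsd4 (4.72 ± 0.29 and 4.13 ± 0.30) on the hindbrain side. On the telencephalic side were Dmrt3, Emx2, Dmrta2, Six3, Rspo2, Chodl, Vit and the Six3 antisense transcript Six3os1 (-4.19 ± 0.19 and -5.14 ± 0.20). In all 677 genes were called in the same direction in both, 391 higher in the hindbrain against 47.5 expected if the calls were independent (odds ratio 40.3) and 286 lower against 23.6 (odds ratio 62.6). Both comparisons used the same filter and the same estimate of each gene's spread. Their calls are therefore not independent, and the expected counts and odds ratios are a reference only. Without genes depleted by the sort, such as Aldh1a2, the endothelial Cdh5 and the mesenchymal Col1a1 and Col6a2, 509 were shared. The 677 made up 74.6% of the higher and 74.3% of the lower calls of whole tissue, and 7 genes were called in opposite directions. The fold changes correlated across the 15698 genes at a Pearson r of 0.51 and a Spearman rho of 0.49, where genes are not independent replicates. The shared count was 262 without telencephalic whole replicate 1, 333 without telencephalic whole replicate 2, 449 without hindbrain whole replicate 1, 380 without hindbrain whole replicate 2 and 208 against a fold change of 1.5.

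**Figure D3:**
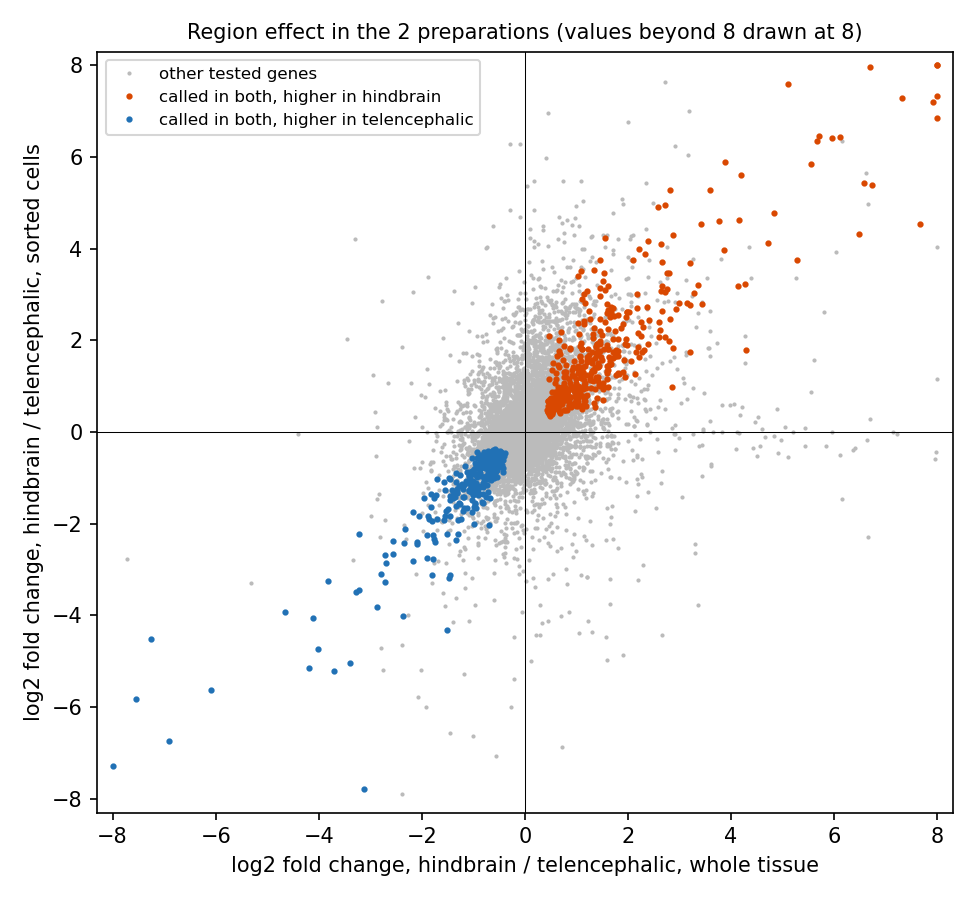
Region effect of each tested gene in whole tissue (horizontal axis) and in sorted cells (vertical axis) as log2 fold change of hindbrain over telencephalic, where genes with 0 counts in a group are drawn at fitted values that are not estimates. The 391 genes called higher in both and the 286 called lower in both are coloured.

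The region effect averaged over both preparations again held the roof plate ligand gene Gdf7 at 8.01 ± 0.37 (adjusted p = 3.35e-08) on the hindbrain side. The guidance ligand Slit3 was lower in the hindbrain, at -1.49 ± 0.08 (adjusted p = 7.59e-08). Of the genes tested 2899 were called, 1671 higher and 1228 lower. The count was 1703 without telencephalic whole replicate 1, 1914 without telencephalic whole replicate 2, and 702, 509 of them higher, against a fold change of 1.5. With library totals as the scale the median gene shifted by 0.14 and 79.7% of the called genes were higher instead of 57.6%.

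The interaction asked whether the region effect differed between sorted cells and whole tissue. The positive calls with the smallest adjusted p were vascular and stromal: the pericyte genes Abcc9 (2.25 ± 0.21), Pdgfrb (1.97 ± 0.19) and Rgs5 (3.28 ± 0.34), the endothelial sialomucin Emcn (2.05 ± 0.20) and the matrix genes Hmcn1 (2.46 ± 0.23) and Nid1 (1.99 ± 0.22) were more hindbrain-biased in sorted cells. Pdgfrb stood at 94.5 ± 4.1 and 88.0 ± 3.0 CPM in telencephalic and hindbrain whole tissue, and at 28.1 ± 3.4 and 103 ± 15 CPM in the sorted cells. Ly6a (-2.69 ± 0.28), the monoamine oxidase Maob (-2.92 ± 0.38) and Wdr72 (-1.95 ± 0.23) went the other way, and so did Reln, an extracellular guide of migrating neurons (-3.22 ± 0.42). Wdr72 stood at 7.43 ± 0.57 and 24.4 ± 0.70 CPM in whole tissue against 44.1 ± 1.9 and 37.2 ± 6.9 CPM in sorted cells. Macrophage markers had 5 of 15 with a positive interaction and 10 not called, with a list median of 1.85 (13 when adjusted over the list alone; camera adjusted p = 1.57e-24, or adjusted p = 0.0121 with an estimated correlation). Mural markers had 5 of 12 positive (9 when adjusted over the list alone; camera adjusted p = 6.13e-25, or adjusted p = 0.00926 with an estimated correlation) and endothelial markers 4 of 14 (6 when adjusted over the list alone; 5.46e-12, or adjusted p = 0.0121 with an estimated correlation). Mesenchymal markers had 3 of 15 positive (10 when adjusted over the list alone; 5.46e-12, or adjusted p = 0.116 with an estimated correlation). Neuronal markers had 1 of 14 negative (6 when adjusted over the list alone; camera adjusted p = 8.73e-08, or adjusted p = 0.0438 with an estimated correlation). Immediate early genes had 2 of 20 positive (4 when adjusted over the list alone; 3.84e-09, or adjusted p = 0.2 with an estimated correlation). Motile cilia genes had 0 of 22 called (camera adjusted p = 0.0195, upward; 0 when adjusted over the list alone; adjusted p = 0.584 with an estimated correlation). Oxidative phosphorylation had 0 of 18 (0.0159, downward; 0 when adjusted over the list alone; adjusted p = 0.584 with an estimated correlation). The cilia call was lost without telencephalic whole replicate 1 (0.219), hindbrain whole replicate 2 (0.0884), telencephalic sorted replicate 1 (0.163) or hindbrain sorted replicate 2 (0.395). The oxidative phosphorylation call was lost without telencephalic whole replicate 2 (0.154), hindbrain whole replicate 1 (0.183), telencephalic sorted replicate 1 (0.146) or hindbrain sorted replicate 1 (0.117).

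The list test called no difference between preparations for the positional lists, with camera adjusted p of 0.74 for Hox genes, 0.0978 for hindbrain and boundary regulators, 0.359 for forebrain regulators and 0.741 for Hedgehog signalling. The median, mean and test differed in sign for the forebrain, Hedgehog, ion transport, secreted factor and erythroid lists. The regulator list passed without hindbrain sorted replicate 2 (0.0339). The interferon response list was not called (0.0629) but passed with brain as a block (0.0166) and without telencephalic sorted replicate 2 (0.000853) or hindbrain sorted replicate 1 (0.00114). Cell cycle genes (0.192) passed without the same libraries (0.0269 and 0.0052), and choroid epithelial identity (0.117) without telencephalic whole replicate 1 (0.0495). The interaction was called for 211 genes, 173 positive and 38 negative. With brain as a block, which pairs the regions, the count was 337. It was 335 with DESeq2, 441 without the low-count filter and 92 against a fold change of 1.5. Leaving out 1 library gave 81 and 58 (telencephalic whole replicates 1 and 2), 124 and 133 (hindbrain whole replicates 1 and 2), 98 (telencephalic sorted replicate 1) and 473, of which 340 positive and 133 negative (hindbrain sorted replicate 2). With library totals as the scale the median gene shifted by 0.12.

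In telencephalic choroid plexus the preparations were compared to see what the sort of reporter-positive cells enriched and depleted. Most vascular markers were lower, to differing degrees. The endothelial genes Esm1 (66.3 ± 5.0 to 0.344 ± 0.048 CPM, -7.54 ± 0.27, adjusted p = 8.93e-09) and Pecam1 (62.0 ± 0.85 to 0.785 ± 0.47 CPM, -6.42 ± 0.26, adjusted p = 1.05e-08) were nearly lost from sorted cells, whereas Kdr fell from 226 to 97.5 CPM. Lower too were the matrix gene Sparcl1 (-6.74 ± 0.27) and Igfbp3 (-6.63 ± 0.31). All 14 endothelial markers were lower (14 when adjusted over the list alone; camera adjusted p = 3.28e-73, or adjusted p = 0.000933 with an estimated correlation). So were 10 of 12 mural markers, with Rgs5 at -5.33 ± 0.27 (10 when adjusted over the list alone; 6.54e-23, or adjusted p = 0.01 with an estimated correlation). Macrophage markers had 13 of 15 lower, with C1qb at -2.45 ± 0.19 (13 when adjusted over the list alone; 1.84e-10, or adjusted p = 0.0593 with an estimated correlation), and mesenchymal markers 10 of 15, with Col3a1 at -1.74 ± 0.20 (11 when adjusted over the list alone; 5.95e-07, or adjusted p = 0.149 with an estimated correlation). Neuronal markers had 8 of 14 lower, with the microtubule gene Dcx at -2.16 ± 0.19 (10 when adjusted over the list alone; 2.46e-05, or adjusted p = 0.114 with an estimated correlation). Progenitor and glial markers had 5 of 12 lower and 1 higher, with the intermediate filament gene Nes at -3.96 ± 0.24 and Dbi at 0.90 ± 0.13 (7 when adjusted over the list alone; 0.000924, or adjusted p = 0.138 with an estimated correlation). Cell cycle genes had 15 of 20 lower, with Mki67 at -2.42 ± 0.21 and the topoisomerase Top2a at -1.88 ± 0.28 (15 when adjusted over the list alone; 7.71e-08, or adjusted p = 0.128 with an estimated correlation).

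Immediate early genes rose in telencephalic sorted cells. Fos, an AP-1 transcription factor induced within minutes of stimulation, rose from 0.847 ± 0.012 to 184 ± 25 CPM (7.75 ± 0.26, adjusted p = 8.93e-09), Egr1 from 12.9 ± 3.0 to 317 ± 26 CPM (4.60 ± 0.18, adjusted p = 1.05e-08) and Fosb 277-fold (95% counting interval 94.6 to 1350). Of 20 immediate early and heat shock genes 17 were higher, 1 lower and 2 not called (19 when adjusted over the list alone; camera adjusted p = 1.63e-38, or adjusted p = 0.0208 with an estimated correlation). Choroid epithelial identity genes had 7 of 16 higher and 9 not called (8 when adjusted over the list alone; 0.00187, or adjusted p = 0.114 with an estimated correlation), with the ageing-related hormone gene Kl at 0.89 ± 0.12, the potassium channel Kcnj13 at 0.84 ± 0.15 and Enpp2 at 0.89 ± 0.12. Ttr was higher at 0.59 ± 0.13 (adjusted p = 0.00586), which was not called with library totals as the scale (0.27, 0.117). Oxidative phosphorylation genes had 7 of 18 higher (11 when adjusted over the list alone; 0.00577, or adjusted p = 0.422 with an estimated correlation). Cox6c changed by 0.77 ± 0.14. The immediate early, endothelial and mural calls held with an estimated correlation. The other 13 lists were not called by camera (adjusted p from 0.103 for ion and water transport to 0.859), and the median, mean and test differed in sign for the secreted factor, forebrain and BMP lists. In this comparison 3517 genes were called, 1551 higher and 1966 lower in sorted cells. The count was 1519 and 1652 without telencephalic whole replicates 1 and 2, 1747 without telencephalic sorted replicate 1, 2181 without telencephalic sorted replicate 2, and 1034, 219 of them higher, against a fold change of 1.5. With library totals as the scale the median gene shifted by -0.32 and 10.5% of the called genes were higher instead of 44.1%.

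In hindbrain choroid plexus the sort depleted endothelial and neuronal transcripts. Esm1 fell from 60.3 ± 11 to 0.457 ± 0.18 CPM (-7.03 ± 0.25, adjusted p = 6.11e-09), Pecam1 from 61.4 ± 1.3 to 1.79 ± 0.22 CPM (-5.09 ± 0.22, adjusted p = 2.73e-08) and the neuronal Stmn2 from 12.4 ± 1.0 to 0.183 ± 0.10 CPM (-6.04 ± 0.54, adjusted p = 1.2e-05). The endothelial transcription factor Sox18 (-6.88 ± 0.30), the prostaglandin transporter Slco2a1 (-6.48 ± 0.29), the glutamate receptor Gria1 (-7.14 ± 0.75) and the neuronal adhesion gene Astn1 (-6.38 ± 0.60) were lower too. All 14 endothelial markers were lower (14 when adjusted over the list alone; camera adjusted p = 8.13e-60, or adjusted p = 0.00142 with an estimated correlation), as were 12 of 14 neuronal markers (13 when adjusted over the list alone; 1.12e-16, or adjusted p = 0.0165 with an estimated correlation). Of the macrophage markers 1 of 15 was lower and 14 were not called, with Csf1r at -0.21 ± 0.16 (0 when adjusted over the list alone; camera adjusted p = 0.86). Mural markers had 6 of 12 lower, with Rgs5 at -2.05 ± 0.21 (8 when adjusted over the list alone; 3.25e-05, or adjusted p = 0.0824 with an estimated correlation). Mesenchymal markers had 4 of 15 lower and 2 higher, with Postn at 0.99 ± 0.15 (8 when adjusted over the list alone; 0.487). Progenitor and glial markers had 6 of 12 lower and 1 higher, with Nes at -3.34 ± 0.22 (8 when adjusted over the list alone; 3.25e-05, or adjusted p = 0.113 with an estimated correlation). Cell cycle genes had 13 of 20 lower, with Mki67 at -1.72 ± 0.19 (14 when adjusted over the list alone; 1.76e-06, or adjusted p = 0.179 with an estimated correlation).

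Immediate early genes rose in hindbrain sorted cells as well, with 19 of 20 higher and 1 not called (20 when adjusted over the list alone; camera adjusted p = 1.61e-79, or adjusted p = 0.0118 with an estimated correlation). Fosb rose from 0.175 ± 0.019 to 117 ± 22 CPM (9.34 ± 0.31, adjusted p = 4.04e-09), Fos from 1.27 ± 0.60 to 255 ± 25 CPM (7.61 ± 0.23, adjusted p = 3e-09) and Egr1 from 12.2 ± 0.52 to 553 ± 100 CPM (5.50 ± 0.19, adjusted p = 4.04e-09). The neutrophil-attracting chemokines Cxcl1 and Cxcl2 were 550-fold (188 to 2670) and 2500-fold (448 to 98700) higher, at 35.9 ± 29 and 54.4 ± 35 CPM, calls lost with limma-voom without a block (adjusted p = 0.0625 and 0.0598). Motile cilia genes had 6 of 22 higher and 16 not called (7 when adjusted over the list alone; 0.00761, or adjusted p = 0.538 with an estimated correlation), with the dyneins Dnahc9 at 0.78 ± 0.10 and Dnahc11 at 0.78 ± 0.11; the list call was lost without hindbrain sorted replicate 2 (0.082). Clu changed by 0.81 ± 0.11 and the angiogenic factor Vegfa by 0.62 ± 0.11. Choroid epithelial identity genes had 6 of 16 higher, 1 lower and 9 not called (7 when adjusted over the list alone; camera adjusted p = 0.0594, or 0.0446 without hindbrain whole replicate 2). Wnt genes had 6 of 16 lower (7 when adjusted over the list alone; 0.0594, and 0.0379 to 0.0449 without 1 of the telencephalic libraries or hindbrain sorted replicate 1). The immediate early, endothelial and neuronal calls held with an estimated correlation. The remaining lists were not called by camera (adjusted p from 0.195 for ion and water transport to 0.947), and the median, mean and test differed in sign for the hindbrain regulator and BMP lists. Ttr was higher at 0.40 ± 0.13 (adjusted p = 0.0389), a call lost with library totals as the scale (0.19, 0.272), with the 4 libraries of the comparison alone (0.0782) and without hindbrain whole replicate 1 (0.11), hindbrain whole replicate 2 (0.115) or hindbrain sorted replicate 2 (0.18, 0.29).

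In hindbrain tissue 3472 genes were called between preparations, 1607 higher and 1865 lower in sorted cells. Of the genes called in both regions 2068 went the same way, 923 higher and 1145 lower against 158.8 and 233.6 expected, and 18 went opposite ways. These expected counts take the calls as independent, which they are not. The comparisons share the estimate of the spread, and the regions came from the same brains. The hindbrain count was 1988 and 1691 without hindbrain whole replicates 1 and 2, 2236 with the 4 libraries of the comparison alone, and 954, 307 of them higher, against a fold change of 1.5. With library totals as the scale the median gene shifted by -0.20 and 20.1% of the called genes were higher instead of 46.3%.

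**Figure D4:**
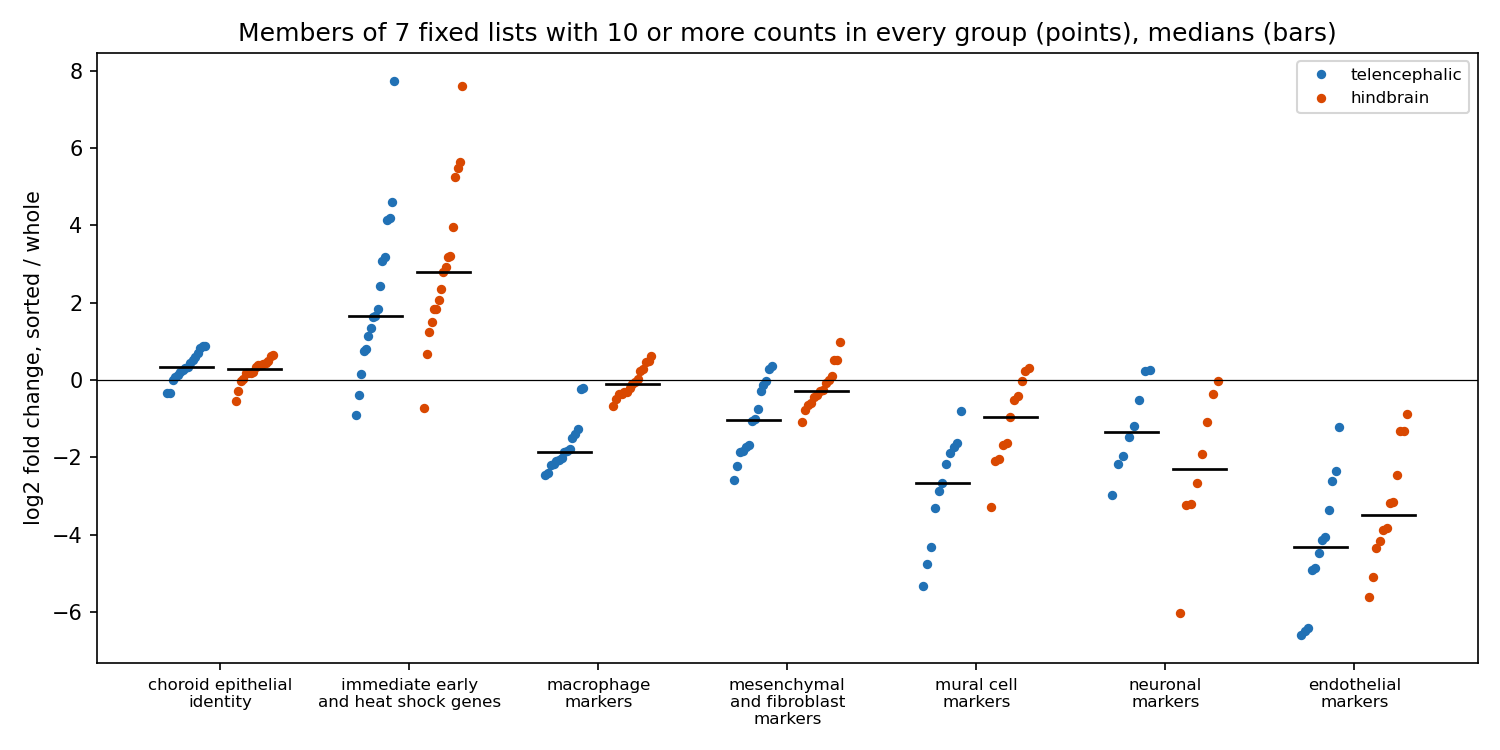
Log2 fold change of sorted cells over whole tissue (vertical axis) for members of 7 fixed lists with 10 or more counts in every group (points), by region, with list medians as bars. Macrophage markers have a median of -1.85 in telencephalic and -0.11 in hindbrain choroid plexus, and immediate early genes of 1.67 and 2.79.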

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

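The list tests on the interaction, and the tests of cell shares, of carry-over and of dissociation given here, were chosen only after the results were seen. The results in this part stand out because the region effect differed between sorted cells and whole tissue by a test of that difference. This held for 211 genes and, by camera, for the lists of mural (adjusted p = 6.13e-25), macrophage (1.57e-24), mesenchymal (5.46e-12), endothelial (5.46e-12) and neuronal markers (8.73e-08), immediate early genes (3.84e-09), oxidative phosphorylation (0.0159) and motile cilia (0.0195). With an estimated correlation the mesenchymal, immediate early, oxidative phosphorylation and cilia calls were lost (adjusted p = 0.116, 0.2, 0.584 and 0.584 with an estimated correlation). The difference of the log2 region effects (sorted minus whole) was above 0 for 27 of the 36 named genes and below 0 for 9.

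Vascular, stromal and macrophage genes were the larger part of the 27 named genes with a positive difference, as the rule for naming draws on those lists. Among all 173 positive calls the mural, macrophage, endothelial and mesenchymal lists held 5, 5, 4 and 3. Of the 173, however, 162 were called lower in sorted cells than in whole tissue of the telencephalic region. Both contrasts use the telencephalic libraries, so part of this overlap is built in. Pericyte genes had values of 2.25 (Abcc9), 1.97 (Pdgfrb), 3.07 (Kcnj8) and 3.28 (Rgs5). Endothelial genes had 1.61 (Cdh5), 2.05 (Emcn), 1.73 (Eng) and 2.26 (Robo4), with 2.55 for the growth factor binding protein Igfbp3. Matrix genes had 1.47 (Col3a1), 1.94 (Col6a1), 1.49 (Col6a2), 2.46 (Hmcn1), 1.99 (Nid1) and 2.86 (Sparcl1), and macrophage genes 1.97 (C1qb), 2.28 (C1qc), 2.1 (Ctss) and 2.05 (Lyve1). Signalling and secreted genes had 1.94 (Hhip), 0.84 (Wnt5a), 1.91 (Rarb), 2.31 (Dlk1), 1.19 (Sod3) and 1.2 (Trf), and the early response genes Klf6 and Zfp36 had 1.89 and 1.54. Values below 0 belonged to Ngp (-4.91), Rspo2 (-1.51), Ly6a (-2.69), Maob (-2.92), Reln (-3.22), Slit3 (-1.01), Wdr72 (-1.95), Gria1 (-5.76) and Pax6 (-3.37). Alternatives for the interaction were examined gene by gene only for the genes that its own naming rule picked. Those were Hmcn1, Abcc9, Emcn, Pdgfrb, Rgs5, Nid1, Ly6a, Wdr72, Maob, Reln, Slit3 and Ngp. For the other genes named here it is not known whether the call holds. The values of Ngp and Slit3 lost their calls without telencephalic whole replicate 2 (adjusted p = 0.0714 and 0.0571), and that of Ngp also without telencephalic whole replicate 1 (0.0664).

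Macrophage, mural and endothelial markers were higher in hindbrain than in telencephalic sorted cells by camera, also with an estimated correlation (adjusted p = 0.0178, 0.015 and 0.0281), whereas the mesenchymal rise and the neuronal fall (5 of 14 lower, 1 higher) were not called with it (0.0527 and 0.179). A lower share of epithelial cells in the hindbrain sort would raise every other cell type alike, but the median difference of the neuronal list lay 2.74 below that of the macrophage list (-2.74), more than the spread of the members (SD 0.86 and 0.55). Macrophages carried into the hindbrain sort may account for the macrophage part: all 15 markers had a difference above 0, and their log2 sorted-to-whole ratios in hindbrain tissue lay close together (SD 0.39, median -0.11), with the most abundant, Mrc1 and Csf1r, at 59.0 ± 19 and 44.9 ± 3.6 CPM in hindbrain sorted cells against 13.4 ± 11 and 14.3 ± 3.4 in telencephalic ones. None of the 15 genes is in another of the lists, all had at least 10 counts in every group, and a sort on the reporter should remove macrophages. A difference between the regions in how their cells express these genes is untested and stays open.

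Immediate early genes rose with the sort in both regions. A larger rise in hindbrain cells was called by camera at its preset correlation only (adjusted p = 3.84e-09, against 0.2 with an estimated correlation and 0.174 by fry, with 2 of 20 members called). By list medians no listed cell type rose as much as the immediate early genes in either region. The 8 lists were epithelial, macrophage, mural, endothelial, mesenchymal, erythroid, neuronal, and progenitor and glial, with members of at least 10 counts in every group. The epithelial one had the highest sorted-to-whole median, 0.33 (SD 0.39) in telencephalic and 0.27 (SD 0.31) in hindbrain tissue. Immediate early genes had 1.67 and 2.79, above the median plus SD of each of the 8 lists in both regions, and macrophages, for example, had -1.85 and -0.11. The filter left 4 of 7 tested erythroid markers, with medians of -1.91 and -2.7, against -0.12 and -0.6 for all 7. It took out Hba-x and Hbb-y, whose counts rose from 77 to 1543 and from 9 to 330 in hindbrain tissue. Of the 7, 2 were called higher and 3 lower there. For erythroid cells the comparison with the SD therefore covers the 4 only. Dissociation and sorting may induce these genes (median of all 20 members 3.06 in hindbrain tissue), but every sorted library and no whole library was handled that way, so handling cannot be told apart from other differences between the preparations, such as cell types outside these lists.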

How the results depend on the processing

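Scaling by library totals, leaving out Ttr and Rn45s, leaving out genes depleted by the sort, limma-voom without a block, and the list tests on the interaction were chosen only after the data were seen. Of 376 named results 355 were called. Of these 239 were called in every alternative counted for them, 116 lost the call in at least 1 and 0 changed direction. This tally leaves out the test against a fold change of 1.5 and the fit without genes depleted by the sort. Some uncalled results gained a call, such as 3 with brain as a block and 4 without the low-count filter. With 1 library left out the remaining one was assumed to vary like those of other groups. Depth limits what can be said of genes near 0, since the smallest library held 8849053 counts. The cause of the changes below was not tested, except that a test against a fold change of 1.5 passes fewer genes by construction. Leaving out a library or using 4 libraries leaves fewer samples for the spread. Counts rose as well as fell in these settings, for example from 909 to 1587 for region in whole tissue with 4 libraries. No cause of such a rise was tested. The order of the region counts also reversed. The shared fit called 909 genes in whole tissue and 2383 in sorted cells, and the 4-library fits called 1587 and 1460. Replicate noise was highest in hindbrain sorted cells (chi-square per degree of freedom 64.49). The counts therefore do not show which preparation differs more by region. Against that fold change the counts were 280 for region in whole tissue, 788 for region in sorted cells, 92 for the interaction, 1034 and 954 for preparation in telencephalic and hindbrain tissue, 702 for the averaged region effect and 208 for genes shared by both preparations. With the 4 libraries of a comparison alone they were 1587 for region in whole tissue, 1460 for region in sorted cells and 2236 for preparation in hindbrain tissue. Without genes depleted by the sort, a filter that shares its sorted libraries with the comparison, region in sorted cells had 1435. The interaction had 335 with DESeq2, 441 without the low-count filter and 337 with brain as a block. Among lists the block, which keeps the pairing of regions, changed 3 calls: choroid epithelial identity (0.0509) and secreted factors (0.0331) in sorted cells and interferon response in the interaction (0.0166). The block moved no other of these counts by over 1.5 times. The filter of 1 CPM ended the list calls of BMP signalling (0.0661) and oxidative phosphorylation (0.0506) in whole tissue and of BMP signalling (0.0503) and choroid epithelial identity (0.053) in sorted cells, and RLE scaling those of choroid epithelial identity and progenitor markers in sorted cells (both 0.05 when rounded). Of the called named values 14 lost their call with the block, all for preparation, where the block also replaced edgeR by limma-voom. All 14 kept their direction, and limma-voom without a block lost the same 14 calls and those of Cxcl1 and Cxcl2 in hindbrain tissue (adjusted p = 0.0625 and 0.0598), so the change of method alone ended them. With the block these were, in telencephalic tissue, Alb (adjusted p = 0.118), Aldh1a2 (0.0762), Cldn11 (0.116), Cxcl1 (0.131), Cxcl2 (0.138), Cxcl10 (0.451), Dlx2 (0.0902), Egr2 (0.0882), Hba-x (0.137), Hoxb1 (0.0812) and Ocln (0.0552), and in hindbrain tissue Cxcl10 (0.228), Mx1 (0.0861) and Tnf (0.133). The report mostly leaves out named genes that lost their call in some alternative, such as Cdh5, Csf1r, Hoxb2, Gli1 and Marveld2 for region in whole tissue, lost in 6, 4, 3, 2 and 2 of 16 alternatives, and Cxcl10 for preparation in telencephalic tissue, lost in 5 of 17.

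With 1 library left out, the counts ranged from 316 to 1341 for region in whole tissue, 1051 to 3253 for region in sorted cells, 58 to 473 for the interaction, 1519 to 4501 and 1691 to 3873 for preparation in telencephalic and hindbrain tissue, 1703 to 3759 for the averaged effect and 262 to 865 for shared genes. Called lists ranged from 9 to 16 for region in whole tissue, 12 to 17 in sorted cells, 10 to 10 and 6 to 8 for preparation in telencephalic and hindbrain tissue, and 6 to 10 for the interaction. Camera with an estimated correlation called 3, 6, 3, 3 and 4 lists in that order, and fry called 14 for preparation in hindbrain tissue and 3 for the interaction.

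The values that changed sign all belonged to genes that were not called, and each range here is over leaving out 1 library. For region in whole tissue they were Abcc9 (-0.04, without hindbrain whole replicate 2, to 0.31), Atp5a1 (-0.09, without hindbrain whole replicate 1, to 0.17, with -0.02 without telencephalic whole replicate 2), Atp5b (-0.06, without hindbrain whole replicate 1, to 0.46) and Rsad2 (-0.02, without telencephalic whole replicate 2, to 0.97). Without telencephalic whole replicate 1 Dusp1 gave 0.08 (lowest -0.18; 0.02 with library totals), Egr1 0.18 (lowest -0.29) and Mrc1 -0.09 (highest 0.23). For preparation in telencephalic tissue Hoxa2, with 1 and 2 counts in the groups, gave -0.45 with the block, -0.46 with limma-voom alone, -0.02 with library totals, -1.05 without telencephalic whole replicate 1 and -2.97 without telencephalic sorted replicate 2 (highest 3.28). In hindbrain tissue Hoxa2 gave -0.04 without sorted replicate 2 (highest 0.44), Hoxb3 -0.42 without sorted replicate 1 (highest 0.57) and -0.01 with library totals, and Mrc1 -0.01 with the block, -0.35 without sorted replicate 1 (highest 0.34) and -0.14 with library totals.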

Other observations

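The tests of solute carriers, of families without genes depleted by the sort, of macrophages, brain or day, and of splits of the libraries in this part were chosen or changed only after the results were seen. Guidance molecules of growing axons and migrating cells were over-represented among the 677 genes called in both region comparisons. The 70 tested genes were ephrins, netrins, Slits, semaphorins and their receptors, with Eph receptors, plexins and neuropilins included. Of these 10 were shared against 3 expected (odds ratio 3.74, 95% confidence interval 1.70 to 7.40, Fisher's exact test, two-sided, adjusted p = 0.00199 over 5 families). None of the 10 was a semaphorin, plexin or neuropilin. Higher in hindbrain choroid plexus were Efna5, Efnb2, Epha4, Epha7, Ntng1, Ntng2, Robo2 and Unc5c, with the Slit receptor Robo2 at 1.92 ± 0.18 in whole tissue and 1.56 ± 0.17 in sorted cells. Lower were Ephb3 and Slit3, the latter at -0.98 ± 0.11 and -1.99 ± 0.11. Efnb2, Epha7, Ntng1 and Unc5c fell at least 2-fold with the sort in 1 region or both, as markers of other cells did. Without such genes 6 of 38 were shared against 1.4 expected (odds ratio 4.79, 1.63 to 11.68, adjusted p = 0.00715). Here and for the families below, that filter shares its libraries with the region comparisons, so it is not an independent check. Collagen chains had 7 of 40 shared against 1.7 expected (odds ratio 4.74, 1.76 to 10.96, adjusted p = 0.00242), with the basement membrane chain Col4a6 at 1.16 ± 0.18 and 1.44 ± 0.17. Col1a1 and Col6a2 of these 7 are also mesenchymal markers, and without depleted genes 4 of 25 were shared against 0.9 expected (odds ratio 4.85, 1.21 to 14.45, adjusted p = 0.023).

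Among membrane transport genes, solute carriers were over-represented as well. The fixed ion and water transport list was not called for region in whole tissue or sorted cells (camera adjusted p = 0.271 and 0.672). Of 278 solute carriers 26 were shared against 12 expected (odds ratio 2.34, 1.49 to 3.54, adjusted p = 0.0012), 10 higher in the hindbrain and 16 higher in the telencephalon (21 of 238 without depleted genes, odds ratio 2.51, 1.51 to 3.98, adjusted p = 0.00194); the symbol pattern that defines the family was narrowed after a first run. The amino acid transporter Slc16a10 was higher in the hindbrain at 1.21 ± 0.11 in whole tissue and 1.58 ± 0.11 in sorted cells. On the telencephalic side were the neutral amino acid transporter Slc6a15 (2330 against 1100 CPM in whole tissue; -1.09 ± 0.11 and -0.95 ± 0.11 in whole tissue and sorted cells), the zinc importer Slc39a10 (-0.88 ± 0.11 and -1.21 ± 0.11), the organic anion transporter Slc22a8 (-0.85 ± 0.12 and -0.95 ± 0.12) and the cystine exchanger Slc7a11 (-0.70 ± 0.15 and -2.02 ± 0.15). Potassium channel subunits had 7 of 61 shared against 2.6 expected (odds ratio 2.90, 1.11 to 6.42, adjusted p = 0.0195), with Kcnd3 at 2.13 ± 0.23 and 1.27 ± 0.22 and the channel-interacting Kcnip1 at -3.83 ± 0.36 and -3.25 ± 0.36. Without depleted genes, Kcnip1 among them, 3 of 33 were shared against 1.3 expected and the family did not pass (odds ratio 2.54, 0.49 to 8.21, adjusted p = 0.161). Cadherins and protocadherins had 6 of 76 against 3.3 expected and did not pass (odds ratio 1.91, 0.68 to 4.39, adjusted p = 0.144; 1.41, 0.16 to 5.50, adjusted p = 0.655 without depleted genes).

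Interferon and chemokine genes were higher in replicate 2 than in replicate 1 of both sorted groups, for 6 genes chosen after their values were seen. The interferon gene Ifnb1 had 0 and 1.86 CPM in telencephalic replicates 1 and 2 and 0.04 and 5.43 CPM in the hindbrain ones, and Cxcl10 had 0.79 and 19.72 against 4.55 and 51.89. The others were Ccl5, Ccl4, Oasl1 and Ifit1, and the lowest log2 difference among the 6 was 3.39 in telencephalic and 3.5 in hindbrain cells (pseudocount 0.05 CPM). The macrophage list differed by less than these 6 genes, with a median of 0.36 (SD 0.88) and 0.1 (SD 0.53). This cannot exclude more macrophages in replicate 2, because the 6 genes were chosen for their values and each group gives 1 library against 1. A first comparison, with the medians of the interferon list (0.64 and 0.43), had decided nothing. The list of sex-linked genes, kept as a check, was detected in every library and split the same way: the Y-linked Ddx3y stood at 20.9 and 54.5 CPM in telencephalic sorted replicates 1 and 2 and at 23.1 and 56.1 CPM in the hindbrain ones, and Xist at 2087.3 and 1578.9 and at 2131.4 and 1261.0 CPM. The 2 sorted brains, or pools, may therefore differ in their mix of sexes, and the deviations of same-brain libraries correlated across genes at 0.14. Whether this goes with the interferon genes was not tested; brain and day of handling are 1 split of the libraries and cannot be told apart, and no biological explanation was tested.

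For the averaged region effect other splits of the 8 libraries into 4 and 4 were fitted with preparation kept in the model. The real split gave 2411 genes in this fit and the highest of the other splits gave 0, among 34 in all. Regions are paired within brains, however, and only 8 of the splits, the real one included, part every pair; of these 1 gave as many genes, which are too few splits for a share under 0.05. The criterion first set, 1 in 20 of all splits, took no account of the pairing and was replaced after its outcome was known. The other splits keep some pairs together, and all but the real one leave the region effect in the spread between libraries.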
